A study of Mus musculus with 18 samples.

How the data were processed

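ATAC-seq was run on 18 samples of mouse ES cells. Wild-type cells were given 1 µM ICRF-193 or DMSO for 24 h or 1 h. Conditional knockout cells, Brg1 fl/fl and Baf53a fl/- by the sample titles, were given 0.8 µM tamoxifen or ethanol for 24 h and then fresh medium for 48 h. The treatment protocol states 24 h of ICRF-193 for all wild-type samples, and the 1 h group was taken from the sample titles, so that every 1 h value rests on those titles. The labels' protocols describe sorting of viable cells, transposition of nuclei and paired-end sequencing. Per the labels, replicates are separate passages of one line, so p-values measure the spread between passages and libraries. The deposited files are 1 peak list per sample, called for each sample rather than on pooled samples. Per the submitters' processing notes, the genome build was mm9 and the tools were Bowtie 0.12.9, MACS2 and edgeR 3.12.1, with no role or order given. Read shifting, blacklists and peak-calling parameters are not given in the sources used here.

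The deposited start and end positions of each peak (other values of the files) were read as the authors give them and are printed counted from 1. The score of each peak is the authors' own value with no unit stated in the deposited files. It runs from about the calling threshold upwards and was used only to rank or filter peaks within a list, as a percentile. The lists contain no read counts, so that read depth is unknown and no interval for counting error can be given. A longer list may come from deeper sequencing, and the number of peaks per list (46431 to 129880) stands beside each comparison for that reason. The supplied gene table follows another build than mm9, so no coordinate was set against it. The planned promoter and gene-list analyses were therefore not run, and the deleted genes could not be checked at their loci.

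Peaks that overlap by 1 bp or more over all 18 lists were merged into regions, and a region counted as detected in a library with 1 or more of its peaks. A region was lost when it had a peak in every control library and in no perturbed library, and gained in the reverse case. Counts were set against every other split of the same libraries into groups of the same size (3 splits of 2 against 2 and 10 splits of 3 against 3). To level list lengths, the comparisons were repeated with the top-scoring peaks of each list up to the length of the shortest list of the contrast: 76898 peaks for ICRF-193 at 24 h, 50611 at 1 h, 46431 for Brg1 and 83918 for Baf53a. Regions shared by the controls were also ordered by mean score percentile into 5 equal classes.

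List measures (log2 number of peaks, percent of peaks on X, median width, percent of peaks of 1 kb or more) were compared by two-sided exact permutation tests within a contrast. Over the 4 contrasts labels were permuted within contrasts (4320 arrangements, smallest p 0.000463), with Benjamini-Hochberg adjustment over the 4 measures. Links between lost or gained regions of 2 contrasts were measured by Mantel-Haenszel odds ratios over 10 strata of score percentile (for gains, strata of detection in the other libraries). Their 95% intervals came from leaving out each of 20 chromosomes in turn and cover variation between chromosomes only, not between libraries. No contrast shares a control library with another.

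Peaks were counted in 1 Mb bins with a mean of 10 or more peaks, scaled by list total as log2((peaks + 0.5) / total × 1000), and fitted with limma 3.58.1 in R 4.3.3 (1 term per group over all 18 libraries, variance trend, Benjamini-Hochberg over 2235 bins, called at an adjusted p under 0.05). A number of peaks per bin is not a read count, so no count model was used. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and interval overlaps were checked against bedtools 2.31.1. On simulated data for the Brg1 contrast (2232 bins, 200 changed), the bin test called 48% of bins with 2-fold rises and 54% with 2-fold falls. It called 10% and 14% with 1.5-fold rises and falls, and 0.25% of unchanged bins. About 1 in 2 simulated changes of 2-fold thus went uncalled. Simulated numbers of peaks followed list length in proportion in every bin, with the same added spread in all libraries. These rates therefore do not cover calls that arise where a short list lacks peaks unevenly over bins. Simulated independent losses gave an odds ratio of 1.04 (0.959 to 1.12) with strata and 1.21 without, and linked losses 4.42. Simulated detection depended on strength alone, so strata could remove the link. Absences between real control libraries stayed linked within strata (odds ratios 1.44 to 4.23). The simulation therefore checks the calculation and gives no level for unlinked losses in the real lists.

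The regions named in the text were chosen by a rule set before the data were examined: in each contrast the 5 lost and 5 gained regions with the highest mean score percentile in the lists that hold them, and among called bins the 5 with the largest rise and the 5 with the largest fall. The text prints part of the regions. Groups, tests and most alternatives were also set before the data were examined. The classes by strength, the equal-number control baselines, the detection of lost regions in other contrasts, and fits without replicate 2 of the 1 h contrast or of Brg1 tamoxifen were added afterwards.

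Whether replicate numbers pair libraries across groups was tested by correlating, over bins, the deviations of same-numbered libraries from their group means. In the 1 h contrast these correlations were 0.151, 0.463 and 0.397, so the numbers were taken to pair the libraries there, on the data alone. In that contrast the blocked fit changed no call. In the deposited names, replicate 1 of each group carries one prefix and the other replicates another, a hint of a batch that each contrast holds in balance.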

Results

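Chromatin accessibility of mouse embryonic stem (ES) cells was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, so that open sites appear as peaks of reads. The study asked how topoisomerase II (TOP2), the enzyme that untangles DNA by passing one duplex through another, and the BAF chromatin remodelling complex act on chromatin. Wild-type cells received 1 µM ICRF-193, a catalytic TOP2 inhibitor, or the solvent DMSO, for 24 h (2 libraries per group) or 1 h (3 libraries per group). The 1 h group follows the sample titles, since the treatment protocol gives 24 h for all wild-type samples. In conditional knockout lines, 0.8 µM tamoxifen activated a Cre recombinase that deletes Brg1, the ATPase of BAF, or Baf53a, an actin-related subunit of BAF, with ethanol as the control (2 libraries per group and line). By the titles the lines are Brg1 fl/fl and Baf53a fl/-. The Baf53a ethanol controls thus already lack 1 allele, and the 2 deletions do not start from matched genotypes. Each of the 18 libraries gave 1 peak list on the mm9 genome build, with 46431 to 129880 peaks over 11.6 to 37.2 Mb. Read depth is unknown, because the lists hold positions and a score per peak and no read counts. Regions are named by mm9 coordinates alone, since a gene annotation of that build was not used here.

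Merging overlapping peaks of all lists gave 377189 regions, of which 18061 (4.79%) held a peak in all 18 libraries and 207226 (54.9%) in 1 library alone. Replicates overlapped only in part. Over base pairs under peaks, the Jaccard index of same-group pairs ran from 0.313 to 0.429 in the Brg1 line, from 0.395 to 0.419 in the Baf53a line, from 0.393 to 0.416 at 24 h of ICRF-193 and from 0.299 to 0.425 at 1 h. The indices between control and perturbed libraries were 0.257 to 0.399, 0.373 to 0.438, 0.342 to 0.412 and 0.275 to 0.436 in the same order, so that the ranges overlapped in each contrast.

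The perturbed groups had fewer peaks on average than their controls in all 4 contrasts, and no single contrast passed its exact test. Brg1 deletion gave 65597 ± 27105 peaks against 96240 ± 15886 in ethanol (SD, n = 2 each), a fold of 0.656, with an exact permutation p of 0.3333, the smallest that 2 against 2 libraries allow. ICRF-193 for 24 h gave 87669 ± 15232 against 112598 ± 20410 in DMSO (SD, n = 2 each; fold 0.779, exact p = 0.6667). ICRF-193 for 1 h gave 82316 ± 27596 against 103307 ± 39002 (SD, n = 3 each), a fold of 0.808. Its exact permutation p was 0.5 (smallest possible 0.1), and 0.25 by exact sign flips within the numbered pairs. Baf53a deletion gave 87844.5 ± 1250.9 against 97210.5 ± 18798 (SD, n = 2 each; fold 0.912, exact p = 1). Over the 4 contrasts together the mean log2 change was -0.35 (two-sided exact stratified permutation p = 0.05972, adjusted p = 0.2389 over the 4 list measures tested). Within replicate numbers, which follow a batch hint in the deposited names, the log2 change was -0.34 and -0.87 after Brg1 deletion, 0.0040 and -0.72 with ICRF-193 for 24 h, -0.27, -0.21 and -0.45 at 1 h, and -0.32 and 0.051 after Baf53a deletion. With single libraries left out, the log2 change ran from -1.04 to -0.17 after Brg1 deletion, from -0.55 to -0.17 with ICRF-193 for 24 h, from -0.67 to 0.011 at 1 h and from -0.33 to 0.066 after Baf53a deletion. The share of peaks on X changed by -0.052 percentage points, the median peak width by -6.5 bp and the share of peaks of 1 kb or more by -0.14 points, with exact permutation p of 0.3472, 0.2269 and 0.5653. These changes were -0.094 points, -45.3 bp and -0.56 points with equal numbers of peaks (exact permutation p of 0.2755, 0.07963 and 0.2755). Equal numbers drop low-scoring peaks from the longer lists and none from the shortest, a perturbed one in each contrast but Baf53a. The cut can itself change the widths, so the larger width changes are not ones corrected for list length.

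**Figure D1:**
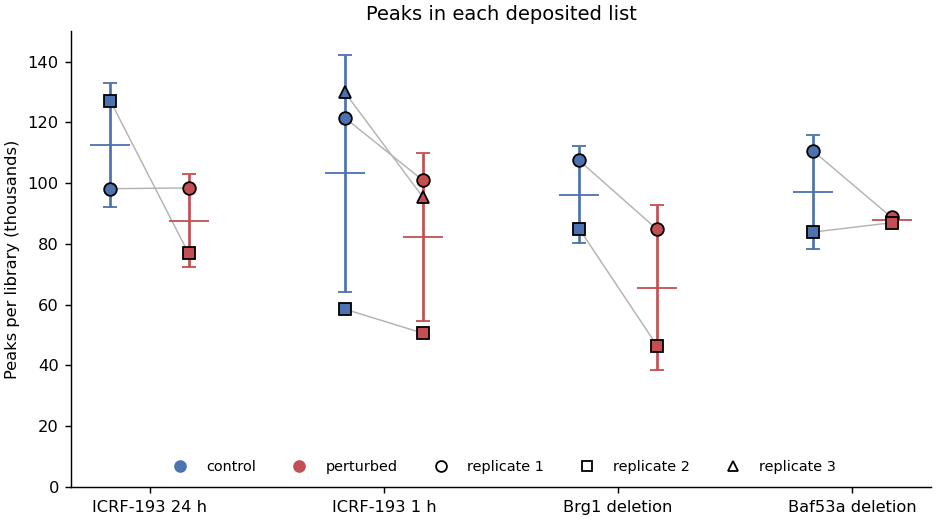
Peaks per library (axis in units of 1000 peaks) for the control and perturbed libraries of each contrast; points are libraries, shapes give the replicate number, grey lines join libraries with the same number, and horizontal marks with bars give the mean and SD. The shortest list, with 46431 peaks, is replicate 2 of Brg1 deletion, and the longest, with 129880, is replicate 3 of DMSO at 1 h.

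After Brg1 deletion, peaks were missing from many accessible regions, mostly weak ones but strong ones among them. Of the 56649 regions with a peak in both ethanol libraries, 13516 (23.9%) had a peak in neither tamoxifen library, and 1571 regions were gained, with a peak in both tamoxifen libraries and in neither ethanol library. The control-shared regions were ordered by score into 5 equal classes. Loss was 48.4% (5483 regions) in the weakest class and 33.1% (3752) in the next. The other splits of these 4 libraries reached 39.1% and 15.4% in these classes. Loss fell to 2.50% in the strongest class. There, 283 of the 11329 regions were lost, against at most 3 (0.0303%) in either direction of the other splits of these 4 libraries. In the opposite direction, 1 of the 6322 strongest regions shared by the tamoxifen libraries was absent from both ethanol libraries. The lost strong regions lay on 20 chromosomes and had a median width of 552 bp, against 935 bp for strong regions detected in all 4 libraries.

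The loss of strong regions did not rest on the short tamoxifen list alone. The replicate 1 tamoxifen list (84763 peaks) was about as long as the replicate 2 ethanol list (85007 peaks). Of the 20179 strongest regions of the replicate 1 ethanol list, 1828 (9.06%) had no peak in the former and 315 (1.56%) none in the latter. Among the 11329 strongest control-shared regions, 323 were absent from the replicate 1 tamoxifen list and 1483 from the replicate 2 tamoxifen list, and the 283 lost regions were absent from both. These comparisons by strength were chosen after the data were examined.

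The strongest region lost after Brg1 deletion, on chromosome 14 from 83408290 to 83408728, held a peak in all 16 other libraries of the series and in 0 of the 2 tamoxifen libraries. Its mean score percentile in the ethanol lists was 98.3 ± 1.12 (SD, n = 2). Next came chromosome 3 from 16382362 to 16383303 (percentile 98.2 ± 0.409), chromosome 14 from 94704580 to 94705308 (97.2 ± 1.14), chromosome 19 from 48724338 to 48725019 (97.2 ± 1.75) and chromosome 3 from 148341792 to 148342461 (97.1 ± 0.225), each with n = 2. Each of these 5 regions held a peak in all 10 wild-type libraries, ICRF-193 libraries included. The strongest gained region, chromosome 17 from 3077827 to 3078038 (93.9 ± 2.99, SD, n = 2), also held peaks in 8 libraries of other lines or treatments. Gained region 3, chromosome 4 from 145438194 to 145438361 (84.6 ± 3.52, SD, n = 2), was detected in the 2 Brg1 tamoxifen libraries and nowhere else.

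Lost and gained regions after Brg1 deletion numbered 15087 together, and the other 2 splits of the same libraries gave 5061 and 6809. With each list shortened to its 46431 top-scoring peaks, 6431 regions were lost and 2606 gained, 9037 together, against 2878 and 2926. The excess of lost over gained regions moved from 8.60 (other splits 3.699 and 8.315) to 2.47 with equal numbers, where the other splits reached 2.29. Without tamoxifen replicate 2, 14858 regions were lost and 24382 gained (13225 and 26003 with equal numbers). A gain then needs a peak in 1 list and a loss a peak in 2, which favours gains by construction. Gains also outnumbered losses without either Baf53a tamoxifen library (25294 against 14085, and 20315 against 10377). These counts therefore do not bear on the direction. With 3 possible splits, no p under 0.05 can be had.

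**Figure D2:**
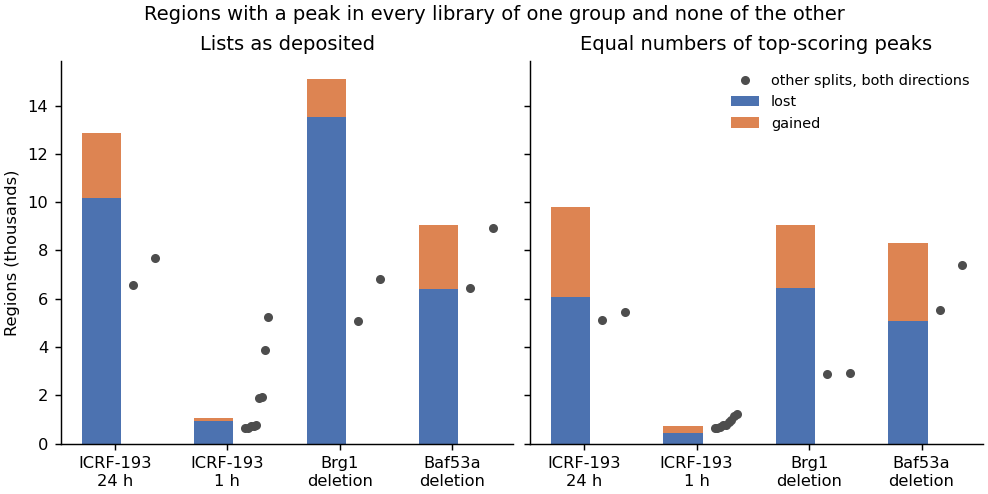
Regions (axis in units of 1000) with a peak in every control and no perturbed library (lost) or the reverse (gained), as stacked bars, for lists as deposited and for equal numbers of top-scoring peaks; dots give both directions together in each other split of the same libraries. The Brg1 bar reaches 15087 regions as deposited and 9037 with equal numbers, where its other splits reach 2926.

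**Figure D3:**
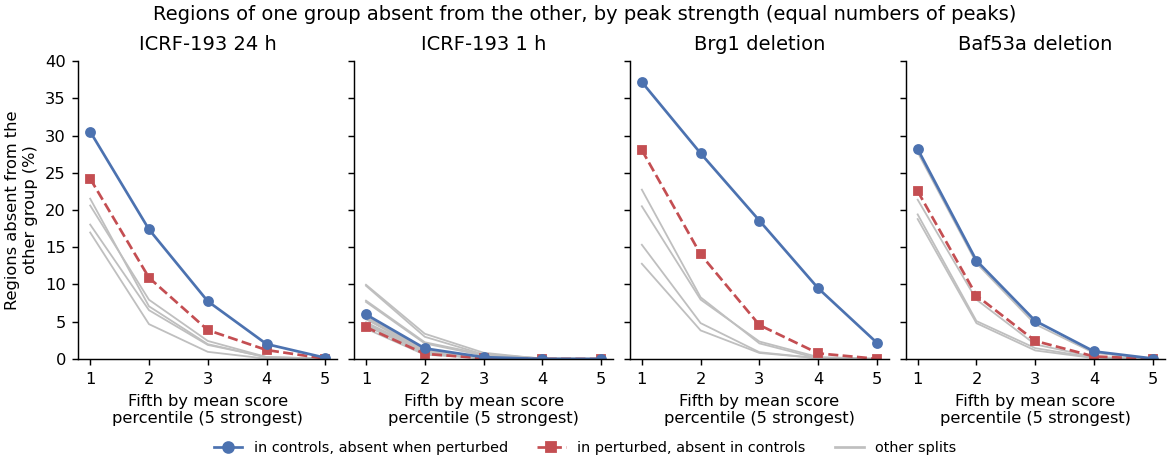
Percent of regions shared by one group that are absent from every library of the other, by class of mean score percentile (1 weakest, 5 strongest), with equal numbers of peaks; blue circles give loss from controls, red squares the opposite direction and grey lines the other splits. In the strongest class, loss after Brg1 deletion is 2.16% and the highest other split 0.0336%.

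**Figure D4:**
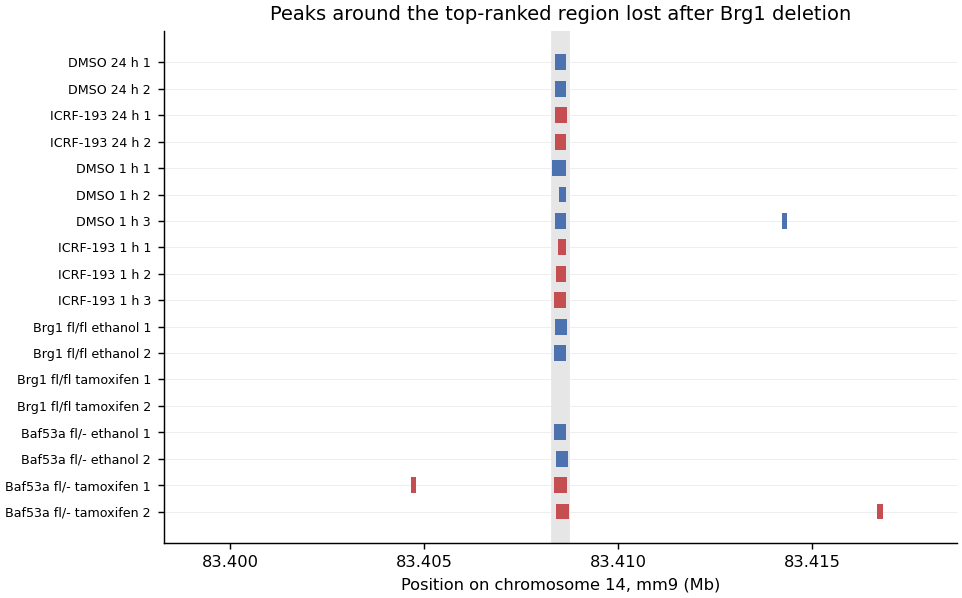
Peaks in each of the 18 libraries around the strongest region lost after Brg1 deletion, on chromosome 14 (mm9, Mb); bars are peaks drawn to scale, blue for control and red for perturbed libraries, and the grey band is the region from 83408290 to 83408728. The 2 tamoxifen libraries of the Brg1 line have no peak in the band and the 16 other libraries have one each.

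Peak density fell over whole megabases after Brg1 deletion. Relative to the total of each list, 64 of 2235 tested 1 Mb bins held fewer peaks and 16 held more (limma, adjusted p under 0.05). In the bin from 55000001 to 56000000 on chromosome 18, the ethanol libraries had 26 and 23 peaks and the tamoxifen libraries 6 and 2 (log2 change -2.02, SE 0.33, limma adjusted p = 0.0006382). The bin from 24000001 to 25000000 on chromosome 11 went from 24 and 18 peaks to 5 and 1 (log2 change -2.28, SE 0.36, limma adjusted p = 0.0006382). Larger falls were fitted on chromosome 14 from 10000001 to 11000000 (-2.83) and chromosome 15 from 19000001 to 20000000 (-2.67), where the replicate 2 tamoxifen list held 0 peaks, and a fall of -2.09 on chromosome 11 from 42000001 to 43000000. Without tamoxifen replicate 2 the changes on chromosomes 14 and 15 shrank to -1.41 and -1.51 and were not called (limma adjusted p = 0.2486 and 0.1242), nor were the -1.40 and -1.12 found with quantile normalization (0.09501 and 0.1386), and the chromosome 11 bin from 42000001 kept its call in 2 of 9 alternative settings. Of these 5 falls, only that on chromosome 18 could be tested with equal numbers of peaks in all 4 libraries, and that on chromosome 15 was not called at equal numbers without tamoxifen replicate 2 (-1.52, limma adjusted p = 0.1535). The largest rises were relative ones in 2 neighbouring bins of chromosome 4. From 146000001 to 147000000 the lists held 70 and 58 peaks in ethanol and 104 and 58 in tamoxifen (log2 change 0.89, SE 0.19, limma adjusted p = 0.008199), and from 145000001 to 146000000 they held 85 and 82 against 118 and 74 (0.77, SE 0.19, adjusted p = 0.02191). Both were called with equal numbers of peaks (1.03 and 0.88, limma adjusted p = 0.002298 and 0.005038). Neither was called without tamoxifen replicate 2 (0.88 and 0.67, limma adjusted p = 0.07198 and 0.244) or without ethanol replicate 1 (0.86 and 0.63, adjusted p = 0.09567 and 0.2498) although the changes stayed of similar size, with an SE of 0.23 in each. With quantile normalization the bin from 145000001 fell to 0.50 (limma adjusted p = 0.07143). Rises of 0.72, 0.68 and 0.67 were fitted on chromosome 13 from 62000001 to 63000000, chromosome 6 from 149000001 to 150000000 and chromosome 12 from 32000001 to 33000000. The number of called bins depended on single libraries: it was 1 higher and 13 lower without tamoxifen replicate 2, 32 and 126 without tamoxifen replicate 1, 0 and 3 without ethanol replicate 1, and 16 and 19 without ethanol replicate 2. Quantile normalization called 12 higher and 18 lower and equal numbers of peaks 36 and 62, where the bins on chromosomes 13 and 12 fell to 0.40 and 0.14 and were not called (limma adjusted p = 0.1837 and 0.6826). The chromosome 18 bin passed in each of its 11 alternative settings, and the chromosome 11 bin from 24000001 in all but that without tamoxifen replicate 2 at equal numbers (-1.57, limma adjusted p = 0.06245).

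After Baf53a deletion, as after Brg1 deletion, the regions without a peak were mostly weak ones. In the strongest class, unlike after Brg1 deletion, loss did not pass the other splits. Of the 57189 regions shared by the ethanol libraries, 6394 (11.2%) were lost, and 2661 regions were gained. Loss fell from 33.4% in the weakest class to 0.0437% in the strongest, where 5 of 11437 regions were lost and the other splits reached 10. Loss did not pass the other splits in the weakest class either, where another split reached 36.4%. That split also reached 16.1% against 15.2% in the next class and 6.34% against 5.98% in the middle one. With equal numbers of peaks the weakest class lost 28.2%, and that split reached 27.8%. The top lost regions were chromosome 14 from 45470426 to 45470600 (percentile 93.5 ± 0.208, SD, n = 2), chromosome 1 from 188753173 to 188753469 (91.6 ± 2.42) and chromosome 13 from 40354064 to 40354491 (90.6 ± 4.28). All 3 also held a peak in both ethanol and in neither tamoxifen library of the Brg1 line. The top gained region was chromosome 14 from 115257012 to 115257332 (87.1 ± 6.79, SD, n = 2), which was detected in both Brg1 ethanol libraries as well.

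The 9055 lost or gained regions after Baf53a deletion were the most of the 3 splits, with 6436 and 8913 in the others, as were the 8304 with equal numbers (5086 lost, 3218 gained; others 5547 and 7405). Another split gave 7130 regions in 1 direction as deposited, more than the 6394 lost. The excess of lost over gained regions was 2.403 as deposited, below both other splits (2.515 and 3.999). With equal numbers it was 1.58, between the others (1.264 and 2.096). With 3 splits, no p under 0.05 can be had here either. No 1 Mb bin was called by limma, with 110 bins at an unadjusted p under 0.05 where 111.8 would be found by chance. A difference between the Brg1 and Baf53a deletions was not called in any bin either, with 243 bins at an unadjusted p under 0.05.

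With ICRF-193 for 24 h, 10168 of the 65604 regions shared by the DMSO libraries (15.5%) were lost and 2678 regions were gained. Loss fell from 40.8% of the weakest class to 3.117% of the class next to the strongest and 0.175% of the strongest, where 23 of 13120 regions were lost and the other splits reached 5. In the weakest class the other splits reached 33.6%. The top lost regions were chromosome 17 from 18092206 to 18092594 (percentile 93.7 ± 2.58, SD, n = 2), chromosome 16 from 27905840 to 27906872 (93.3 ± 0.712) and chromosome 4 from 63868383 to 63869001 (93.1 ± 4.98). All 3 held a peak in the 3 DMSO libraries of the 1 h experiment, and the chromosome 4 region was also absent from both Brg1 tamoxifen libraries. Chromosome 1 from 164439385 to 164439927 was the top gained region (90.6 ± 4.57, SD, n = 2), with no peak in any of the 5 DMSO libraries.

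Lost and gained regions at 24 h numbered 12846, against 6559 and 7700 in the other 2 splits. With 76898 peaks per list, 6085 were lost and 3705 gained, 9790 together, against 5097 and 5446. The excess of lost over gained regions was 3.797 as deposited, inside the range of the other splits (1.03 to 4.40), and 1.64 with equal numbers (others up to 1.49). Limma called 3 of the 2235 bins. Peaks were relatively fewer on chromosome 11 from 9000001 to 10000000 (log2 change -0.83, SE 0.18, adjusted p = 0.04712) and chromosome 5 from 86000001 to 87000000 (-0.83, SE 0.18), and more frequent on chromosome 19 from 16000001 to 17000000 (0.70, SE 0.15). The log2 changes stayed about as large with equal numbers of peaks (-0.83, SE 0.21; -0.74, SE 0.19; 0.78, SE 0.19) with larger SE, and none of the 3 was called (limma adjusted p of 0.09289, 0.1085 and 0.09289). No bin was called when any of the 4 libraries was left out, with log2 changes in these 3 bins of -0.94 to -0.72, -1.002 to -0.65 and 0.62 to 0.79.

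With 1 h of ICRF-193 few regions were lost or gained, under a stricter rule than elsewhere. A region had to be present in all 3 libraries of one group and absent from all 3 of the other. The other contrasts have 2 libraries per group, so these counts cannot be set against theirs. Of the 41365 regions shared by the 3 DMSO libraries, 942 (2.28%) were lost, 791 of them in the weakest class and 0 in the strongest, and 129 regions were gained. The top lost region was chromosome 7 from 143044955 to 143045515 (percentile 83.3 ± 4.06, SD, n = 3), which held a peak in all 4 libraries of the 24 h experiment, ICRF-193 included. The top gained region was chromosome 6 from 127566477 to 127566928 (67.8 ± 6.96, SD, n = 3), which held a peak in both DMSO libraries of the 24 h experiment. The 1071 lost or gained regions were matched or passed by 5 of the 10 splits of the 6 libraries, the real one included, and the highest other split gave 5255. Replicate numbers were taken to pair the libraries of this contrast, on the data alone. ICRF-193 replicate 1 correlated better with DMSO replicate 3 (0.191) than with DMSO replicate 1 (0.151), so this pairing is uncertain. Among the 4 splits that part all 3 numbered pairs the real one was the largest (others 649, 784 and 638, and with equal numbers 731 against 649, 705 and 660). Limma called 0 of 2235 bins, with 61 at an unadjusted p under 0.05 and 111.8 by chance. Libraries of replicate 2 had 58532 and 50611 peaks, and without both of them 8932 regions were lost and 1859 gained. These counts rest on 2 libraries per group, as do the 10168 and 2678 at 24 h. This alternative was chosen after the list lengths were seen. The difference between 24 h and 1 h of ICRF-193 was called in 0 bins (limma, 96 at an unadjusted p under 0.05).

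Regions lost in one BAF deletion were often lost in the other. Among 43452 regions with a peak in all ethanol libraries of both lines, 6471 were lost after Brg1 deletion and 2038 after Baf53a deletion, and 1148 after both, against 303.5 for independent losses. With regions matched for score in 10 strata the odds ratio was 4.02 (95% interval 3.68 to 4.40 over chromosomes). Regions lost with 24 h of ICRF-193 were also linked to both deletions. Of 45634 regions, 1471 were lost with ICRF-193 and after Brg1 deletion against 556 for independent losses (odds ratio 2.29, 2.12 to 2.47), and of 44483 regions, 621 were lost with ICRF-193 and after Baf53a deletion against 162 (2.10, 1.88 to 2.33). The 1 h losses gave odds ratios of 3.89 (3.08 to 4.91) with the 24 h losses, 1.95 (1.56 to 2.44) with Brg1 and 2.37 (1.73 to 3.25) with Baf53a.

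Untreated libraries set the level that such links reach with no perturbation. For each contrast's lost regions, the odds ratio of absence from a perturbed library given a control library was compared with that of absence from another control library. Regions lost after Brg1 deletion gave 2.89 to 3.57 from ethanol to tamoxifen libraries of the Baf53a line and 1.95 to 2.73 between its ethanol libraries. Regions lost after Baf53a deletion gave 3.06 to 3.78 in the Brg1 line against 2.05 to 2.29. Regions lost with 24 h of ICRF-193 gave 2.14 to 2.37 in the Brg1 line against 1.66 to 1.85. In the reverse direction, regions lost after Brg1 deletion gave 1.87 to 2.34 from DMSO to ICRF-193 libraries at 24 h, which overlapped the 1.57 to 1.962 between DMSO libraries. Between 24 h of ICRF-193 and Baf53a deletion the values overlapped as well (1.92 to 2.19 against 1.81 to 2.12, and 1.76 to 2.39 against 1.86 to 2.06), and no link of the 1 h contrast lay above all control values. Regions lost at 1 h lay below all control values in the Brg1 line (2.06 to 2.21 against 2.67 to 2.70). They did so at 24 h of ICRF-193 too (2.85 to 3.66 against 3.67 to 4.07). With equal numbers of peaks, regions lost with 24 h of ICRF-193 lay above in the Brg1 line (2.62 to 3.03 against 1.40 to 1.70) and in the Baf53a line (1.95 to 2.14 against 1.66 to 1.83), while at 24 h of ICRF-193 the values still overlapped for regions lost after Brg1 deletion (2.55 to 3.22 against 1.62 to 2.69) and after Baf53a deletion (1.77 to 2.46 against 1.66 to 2.22). Each 24 h or deletion contrast has 2 control libraries, read in both directions, so that its control values are not independent and carry no p.

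**Figure D5:**
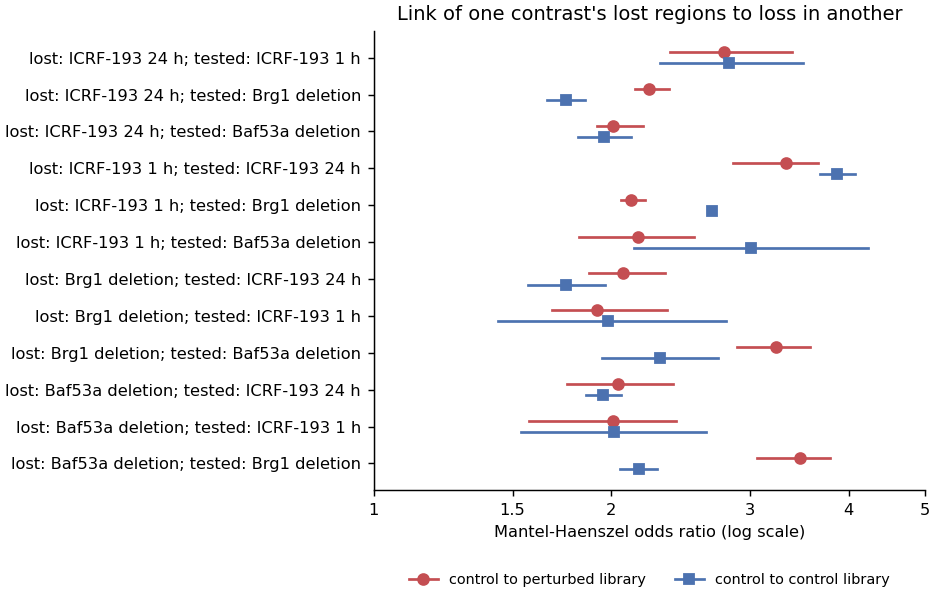
Mantel-Haenszel odds ratios (log scale) that tie regions lost in one contrast to absence from a library of another, matched for score; red circles with ranges run from control to perturbed libraries and blue squares with ranges from control to control libraries. Red and blue ranges stand apart, with red higher, for Brg1 and Baf53a deletion in both directions and for regions lost with 24 h of ICRF-193 tested in the Brg1 line. They stand apart with red lower for regions lost at 1 h tested at 24 h of ICRF-193 and in the Brg1 line.

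Gained regions were shared between the BAF deletions too, in small numbers. Of 692 regions gained after Brg1 deletion and 1443 after Baf53a deletion among 207758 without a peak in any ethanol library, 46 were gained in both against 4.81 for independent gains (odds ratio 4.17, 3.02 to 5.75). No level between untreated libraries was computed for gains. Whether this or the other gained overlaps pass such a level is therefore not known. The odds ratio fell when any of the 4 tamoxifen libraries was left out, to 1.07 (0.862 to 1.32) and 1.55 without replicate 1 and 2 of the Brg1 line and to 1.25 and 1.78 without those of the Baf53a line. ICRF-193 for 24 h shared 22 gained regions with Brg1 deletion (odds ratio 1.04, 0.627 to 1.73) and 39 with Baf53a deletion (1.42, 1.03 to 1.95), and these values fell below 1 when any perturbed library was left out (to between 0.439 and 0.813, and between 0.564 and 0.7503) but not when a control library was. They were 1.54 (1.17 to 2.01) and 2.15 (1.83 to 2.52) with equal numbers of peaks. The 1 h gains shared 2 or 3 regions with each other contrast.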

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

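The tests in this part were chosen after the results were seen. A difference between perturbations was called by limma in a few 1 Mb bins. The change after Brg1 deletion differed from that with 24 h of ICRF-193 in 5 bins and from that with 1 h of ICRF-193 in 3 bins, each time with the Brg1 value lower. On chromosome 18 from 55000001 to 56000000 the log2 change was -2.02 after Brg1 deletion, 0.41 with ICRF-193 for 24 h (difference 2.43, SE 0.47, limma adjusted p = 0.02052) and -0.022 for 1 h (difference 2.00, SE 0.43, adjusted p = 0.0384). On chromosome 11 from 24000001 to 25000000 the 24 h change was 0.030 against -2.28 (adjusted p = 0.04283), and on X from 11000001 to 12000000 it was 0.35 against -1.82 (adjusted p = 0.03382). The other 2 bins lay on chromosome 7 from 90000001 to 91000000 (0.20 against -1.06) and chromosome 12 from 16000001 to 17000000 (0.58 against -0.66). The contrasts come from different cell lines, so that the line and the perturbation cannot be separated in these differences.

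The wild-type and knockout lines differed on the sex chromosomes. All 8 knockout-line lists held peaks on Y, from 38 to 52 per list, and the 10 wild-type lists held 0. On X, the wild-type lists held 3.739% to 4.13% of their peaks and the knockout-line lists 1.787% to 2.1%. List length as the source is argued against by these values, since the lengths of the 2 sets overlap and the lowest wild-type share (3.739%) stays above the highest knockout-line share (2.1%). The same sex chromosomes in both sets are argued against by the peaks on Y in 8 of 8 knockout-line lists against 0 of 10, and by the X shares. These values also raised the question, so no separate test was made. The labels used here give no sex for the lines. Control and perturbed libraries of each contrast come from the same line, so the difference between lines lies outside each contrast and bears on comparisons of X between lines.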

How the results depend on the processing

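Of 725 alternative values, 546 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times the main value. Some could not differ. Each peak lies inside its merged region, so asking for a shared 0.5 of the shorter returned the same values. Loss in each numbered pair restates the main rule, and 20 strata left gained overlaps unchanged. Exact permutation tests of 2 against 2 libraries cannot pass 0.05 (smallest p 0.3333). The totals given here count all of these. All 93 alternatives of the overlap of lost regions kept an odds ratio and interval above 1. The odds ratios were 2.88 to 8.75 for Brg1 and Baf53a, 1.85 to 4.73 for 24 h of ICRF-193 and Brg1, and 1.60 to 5.84 for 24 h of ICRF-193 and Baf53a. Absences between control libraries reached odds ratios of 1.44 to 4.23 with no perturbation, so a value above 1 does not show a link beyond that level. For gained regions, 70 of 93 kept their direction and their side of the threshold, among them alternatives of 2 pairs without a link as deposited (odds ratios 1.04 and 1.64). Of 80 checks of the named regions 75 kept all 5, and named bins kept their call in 83 of 141 checks. The planned promoter and gene-list alternatives were not run. Read depth is unknown and limits every count. The fits without both replicate 2 libraries of the 1 h contrast, those without Brg1 tamoxifen replicate 2 at equal numbers, and the detection tests were chosen after seeing the data. Where no reason is given, the cause was not tested.

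With equal numbers of peaks, lost regions were 6085 for ICRF-193 at 24 h, 452 at 1 h and 6431 for Brg1, and gained regions 279 at 1 h and 2606 for Brg1. The gained overlap of ICRF-193 at 24 h and Brg1 was 1.54, that of 1 h and Brg1 1.11. Detection of 24 h losses elsewhere moved to -3.38 (exact permutation p = 0.04167, adjusted 0.08334) and of 1 h losses to -1.88. With only the peaks above each list's median score, and so fewer peaks, lost and gained regions were 6078 and 1464 at 24 h, 473 and 33 at 1 h, 8059 and 738 for Brg1, and 3361 and 1478 for Baf53a. The gained overlaps of 1 h with Brg1 and with Baf53a were 0, and the change of the X share 0.016 points. With peaks up to 200 bp apart merged, gained overlaps were 5.80 for the 2 ICRF-193 times, 1.32 for 24 h and Baf53a, and 2.71 for 1 h and Brg1. Without strata, gained overlaps were 3.57 for 24 h and Brg1 and 7.62 for 1 h and Baf53a.

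With a replicate block, the log2 change in the number of peaks over the 9 numbered pairs stayed at -0.35 with an exact sign-flip permutation p of 0.01562, and called bins were 4 higher and 12 lower at 24 h and 72 and 178 for Brg1. Outside the 1 h contrast the same-numbered libraries share only a number (correlations of deviations 0.0152, 0.0756 and 0.0251). At 1 h, DMSO replicate 3 correlated better with ICRF-193 replicate 3 (0.397) than with 1, while ICRF-193 replicate 1 correlated better with DMSO replicate 3 (0.191) than with its own number (0.151). The block changed no other call.

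Called bins at 24 h of ICRF-193, higher and lower, were 0 and 1 with 500 kb bins, 0 and 0 without a filter on low bins, 3 and 7 with a pseudocount of 2, 2 and 2 with median-ratio scaling, 1 and 1 with quantile normalization, 1 and 0 with equal numbers and 0 and 0 above the median score. For Brg1 they were 25 and 62 with 500 kb bins, 12 and 18 with quantile normalization, 36 and 62 with equal numbers (32 of the 65 calls that were tested again shared, all 65 in the same direction), 12 and 38 above the median score, and 0 and 4 without tamoxifen replicate 2 at equal numbers.

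Leaving out 1 library at a time leaves fewer lists to satisfy, so that counts of lost and gained regions rise by construction: 14219 to 51458 lost and 4375 to 25460 gained at 24 h, 1130 to 8122 and 149 to 1677 at 1 h, 14858 to 48907 and 2828 to 24382 for Brg1, and 10377 to 36540 and 3905 to 25294 for Baf53a. With a perturbed library left out, a gain needs a peak in fewer lists than a loss, so the balance shifts to gains by construction. Without Brg1 tamoxifen replicate 2, gained regions (24382, and 26003 at equal numbers) outnumber lost ones (14858), while without tamoxifen replicate 1, 28227 were lost and 9539 gained. Gains also outnumber losses without ICRF-193 replicate 2 at 24 h (25460 against 14219) but not without replicate 1 (15843 against 20660). They do so without either Baf53a tamoxifen library. Without both replicate 2 libraries at 1 h, 8932 were lost and 1859 gained, and the gained overlap with Baf53a was 1.71. The log2 change in the number of peaks ran from -0.46 to -0.24 over all contrasts, with an exact permutation p of 0.01574 without DMSO 1 h replicate 2, 0.03704 without Brg1 tamoxifen replicate 1 and 0.03519 without Baf53a ethanol replicate 2. It ran from -1.04 to -0.17 for Brg1, from -0.55 to -0.17 at 24 h, from -0.67 to 0.011 at 1 h and from -0.33 to 0.066 for Baf53a, and the share of wide peaks from -0.28 to 0.0017 points. Gained overlaps ran from 1.60 to 6.38 for the ICRF-193 times, 0.439 to 1.26 for 24 h and Brg1, 0.564 to 1.53 for 24 h and Baf53a, 1.43 to 8.35 for 1 h and Brg1, 0.855 to 1.95 for 1 h and Baf53a, and 1.07 to 4.65 for Brg1 and Baf53a. Called bins ran from 0 to 0 in each direction at 24 h, and from 0 to 32 higher and 3 to 126 lower for Brg1. A group left with 1 library was assumed to vary like the others.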

Other observations

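Strong regions lost after Brg1 deletion were detected in a lower share, on average, in the ICRF-193 libraries at 24 h and the Baf53a tamoxifen libraries than in their controls. Of the 283 strong regions lost after Brg1 deletion, 97.2% ± 2.50 had a peak in the DMSO libraries at 24 h and 80.4% ± 5.75 in the ICRF-193 libraries (SD, n = 2 each). In the Baf53a line the shares were 96.6% ± 3.75 in ethanol and 82.2% ± 7.75 in tamoxifen (SD, n = 2 each). At 1 h they were 89.5% ± 12.7 in DMSO and 86.8% ± 12.9 in ICRF-193 (SD, n = 3 each). A single control library, DMSO at 1 h replicate 2, stood at 74.9%. Only 19 of the 283 were lost outright after Baf53a deletion, and 201 held a peak in all 4 libraries of that line. These shares were chosen after the data were examined and carry no test of their own.

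In all, 148 regions were lost in all 3 of Brg1 deletion, Baf53a deletion and 24 h of ICRF-193, out of 38787 with a peak in every control of these contrasts. Independent losses would give 7.19, and independent losses within strata of score 38.0. Absences are linked between untreated libraries of these contrasts too (odds ratios 1.57 to 2.73), and no such level was computed for regions lost in all 3. The highest-ranked were chromosome 13 from 3530316 to 3530810, chromosome 12 from 117778685 to 117779336 and chromosome 15 from 88746644 to 88747185, with mean control percentiles of 74.9, 74.7 and 74.5.

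Among the tests below, those on list length, on tamoxifen, on ICRF-193 losses in the Brg1 line, on detection in other contrasts and on splits of regions at 1 h were chosen after the results were seen. All regions lost after Brg1 deletion were followed in the 14 libraries of the other contrasts, against kept regions of the same strength. The change of their detection from control to perturbed libraries, less that of the kept regions, was -8.23 percentage points (exact stratified permutation p = 0.01944, adjusted p = 0.07776 over 4 such tests). The part from Baf53a deletion was -12.0 points, from 24 h of ICRF-193 -9.76 and from 1 h -2.97. With equal numbers of peaks the value was -9.21 (exact permutation p = 0.04167, adjusted p = 0.08334), so the result misses the threshold after adjustment. Regions lost after Baf53a deletion gave -3.12 (exact permutation p = 0.3139), those lost at 24 h -0.91 (p = 0.5472) and those lost at 1 h 0.81 (p = 0.75). The part of the 24 h losses was 2.05 points in the Brg1 line, -1.70 in the Baf53a line and -3.09 at 1 h, that of the Baf53a losses -4.41 in the Brg1 line, -2.92 at 24 h and -2.04 at 1 h, and that of the 1 h losses 8.80 in the Brg1 line, 0.24 in the Baf53a line and -6.60 at 24 h.

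Brg1 deletion and 24 h of ICRF-193 each gave more lost or gained regions than other splits of their libraries, and their perturbed lists were shorter. Shorter lists as the whole source are argued against by equal numbers of peaks, with 9037 regions after Brg1 deletion (highest other split 2926) and 9790 with ICRF-193 (highest other split 5446). The direction stays open: the ratio of lost to gained regions at equal numbers was 2.468 after Brg1 deletion (others up to 2.293) and 1.642 with ICRF-193 (others up to 1.492), so that a shorter list and a real excess of loss cannot be told apart by this ratio. The lost strong regions bear on the direction for Brg1, with 146 lost and 1 gained at equal numbers. Over all regions, counts with 1 tamoxifen library left out cannot show the direction, because the rule then favours gains. They were 14858 lost and 24382 gained without tamoxifen replicate 2, and 28227 lost and 9539 gained without replicate 1. Tamoxifen and Cre activation alone as the source of this strong loss are argued against, since the Baf53a line received the same tamoxifen and at least 76.7% of the 283 regions held a peak in each of its tamoxifen lists, while a response of the Brg1 line alone and a part in the weaker losses stay open.

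A shared response of the same regions may underlie the link between the BAF deletions, with weak regions that drop out of any list as a technical alternative and tamoxifen and Cre activation, shared by both deletions, as an untested one. For Baf53a deletion the lowest odds ratio from ethanol to tamoxifen libraries, 2.8871, lay above the highest between ethanol libraries, 2.7323, which met the rule set beforehand. Ranges also stood apart the other way, for 1 h losses in the Brg1 line (2.06 to 2.21 against 2.67 to 2.70). With 1 pair of ethanol libraries per line, such a separation cannot decide, and weak regions stay open. ICRF-193 losses followed in the Brg1 line gave a lowest value of 2.1406 against at most 1.8529 between ethanol libraries, but their detection, less that of kept regions, rose there by 2.05 percentage points (-3.76 with equal numbers of peaks). That rise came from tamoxifen replicate 2, the shortest list (-17.9 points, against -24.8 in tamoxifen replicate 1 and -21.9 and -24.9 in ethanol). In the other direction, regions lost after Brg1 deletion gave a lowest value of 1.8742 in the ICRF-193 libraries at 24 h, below the highest control value of 1.9617 (2.55 and 2.69 with equal numbers). With 2 control libraries per contrast and measures that disagree, a shared target of TOP2 and Brg1 and weak regions cannot be told apart here.

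For 1 h of ICRF-193, 5 of the 10 splits gave as many lost or gained regions as the real one (1071, highest other 5255), and the splits are too few for a share under 0.05. Since the real split called 0 bins, all 10 splits reach that number (highest other 4), which tests nothing. Among the 4 splits that part all 3 numbered pairs, an uncertain pairing read from these data, the real one was the largest (others 638 to 784), again too few for such a share. The 4 largest other splits (1883 to 5255 regions) all put both replicate 2 libraries, which have the shortest lists, on the same side, a structure of these samples. With equal numbers of peaks the same 4 splits stayed the largest (901 to 1204, the real one 731), so levelled list lengths do not remove it.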
